A study of Mus musculus with 6 samples.

How the data were processed

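Poly(A) RNA of 6 liver tumour samples, 3 Myc/NrasG12V and 3 Myc/Akt1, had been sequenced as stranded single-end libraries. The deposited files hold 1 value per gene and library in CPM (reads scaled to a common library total), although the column is named reads. The submitters' processing notes name STAR 2.6.1c, Subread 1.6.3, edgeR 3.22.5 and the build GRCm38. The annotation release, the strand setting and the handling of multi-mapped reads were not given in the sources used here. In each deposited file the CPM values were whole multiples of the value of 1 read, within 0.01 read for 100% of values, so the whole reads were recovered, and no composition factor had been applied. The value of 1 read was 0.0359 to 0.0559 CPM.

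The files list 39179 genes, of which 37607 (96.0%) matched an identifier in GENCODE M21, the source of the coordinates; its build is that named by the submitters, but the release they used is not known. A symbol was missing for 1076 genes, 88 of them tested, which were kept under their identifiers. Of all genes, 23732 had a read in at least 1 library, and 14365 passed the filterByExpr rule of edgeR, which needed 0.457 CPM in 3 libraries and 15 reads in total.

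Groups were compared with limma 3.58.1 (lmFit, eBayes with a trend, two-sided) on log2(CPM + 1), Myc/NrasG12V minus Myc/Akt1, with no other covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The plan fixed before the data were examined was edgeR on counts, or limma on log2(value + 1) if the files held normalized values. They did, so limma was used, and edgeR 4.0.16 on the recovered reads became an added alternative: it called 4893 genes, 2381 higher in Myc/NrasG12V and 2512 higher in Myc/Akt1, 3943 of them shared with limma in the same direction and 0 in the opposite one. R 4.3.3 and DESeq2 1.42.0 were also used. Fold values are ratios of group mean CPM, except that a lower bound against a group with 0 reads uses the reads pooled over each group, and log2 differences are limma estimates with the pseudocount. With 3 against 3 samples an exact permutation test of a single gene cannot give a p below 0.1.

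The comparison, 33 gene lists, the alternatives and the rule for named genes were also fixed then. The rule took Myc, Nras and Akt1; the 10 genes with the largest log2 difference in each direction among changed genes with a mean of at least 5 CPM and groups that did not overlap, leaving out predicted and clone-based symbols; the 4 members of lowest adjusted p of each list that passed the set test and 2 of each other list; and Alb, Afp, Cdkn2a, Xist and Ddx3y. Lists with at least 5 tested members were tested with camera (preset correlation 0.01) on log2(CPM + 1), in place of the planned edgeR log-CPM, with Benjamini-Hochberg adjustment over 31 lists. Cell type lists are bulk markers, and a shift in one is a shift in those genes, not a cell count. Gene families, imprinted genes and blood cell precursor genes were chosen after results had been seen.

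Alternatives were other scaling factors, other filters, other pseudocounts, other tests, the replicate number as a block and leaving out each library. The procedure was tested on simulated data of 14365 genes with 200 changed ones: it recovered 27.3% of 55 genes changed 1.5-fold, 91.8% of 73 changed 2-fold and 100% of 72 changed 4-fold. The changed genes were drawn from those with a mean of at least 5 CPM, in random directions, with 1 common dispersion for all genes. Spread differed between genes in the real data, so recovery there may differ from these rates, above all for genes of low level. There were 18 false calls, 10.5% of the calls, above the nominal rate, and 0 of 20 sets of unchanged genes were called. Genes were simulated independently of each other, so these sets do not test the preset correlation between genes.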

Results

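The data were RNA-seq libraries of liver tumours from C57BL/6 mice. The tumours were made by hydrodynamic injection, a rapid tail vein injection of a large volume that brings DNA into hepatocytes. The DNA held transposons, which insert their cargo into the genome. They encoded Myc with either NrasG12V, an activated form of the small GTPase Nras, or Akt1, a kinase of the insulin and growth factor pathway. There were 3 Myc/NrasG12V and 3 Myc/Akt1 libraries. The deposited values were CPM, reads of a gene scaled to a common library total, from which whole reads could be recovered. The Myc/NrasG12V libraries held 20941840, 21780251 and 17881282 reads for replicates 1, 2 and 3, and the Myc/Akt1 libraries held 23571267, 27865094 and 22005319. At these depths 3 reads in a library, the limit that a count of 0 allows, corresponded to 0.108 to 0.168 CPM. Floors covered counting error only. The labels did not say whether the samples of a group came from separate animals, so the p-values bore only on the spread between these samples. Limma draws the spread of a gene toward that of genes of similar level. Xist, which is expressed in female cells, was at 1800.3 ± 262 CPM (SD, n = 3) in Myc/NrasG12V and 1817 ± 92.8 CPM (SD, n = 3) in Myc/Akt1. The Y-linked gene Ddx3y had 0 reads in all 6 libraries.

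The comparison asked how tumours driven by Myc with NrasG12V differed in mRNA from tumours driven by Myc with Akt1. The transcripts of the delivered oncogenes came first, since they bear on the labels. Nras (ENSMUSG00000027852, chromosome 3, 103058285 to 103067914, GRCm38) was 3.05-fold higher in Myc/NrasG12V, at 171 ± 25.0 CPM (SD, n = 3) against 56.0 ± 4.51 CPM (SD, n = 3), with a limma adjusted p of 2.79e-04. Akt1 (ENSMUSG00000001729, chromosome 12, 112653821 to 112674884) was 4.30-fold higher in Myc/Akt1, at 279.9 ± 33.8 CPM (SD, n = 3) against 65.1 ± 19.1 CPM (SD, n = 3), with a limma adjusted p of 2.63e-04. For both genes every library of one group lay above every library of the other. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), delivered in both groups, was at 153 ± 29.4 CPM (SD, n = 3) in Myc/NrasG12V and 154 ± 55.0 CPM (SD, n = 3) in Myc/Akt1. Its log2 difference was 0.03, with a 95% interval from -0.57 to 0.63 and a limma adjusted p of 0.945. The labels did not give the species of the delivered cDNAs, so these values covered transgene transcripts only as far as their reads map to the mouse genes.

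**Figure D1:**
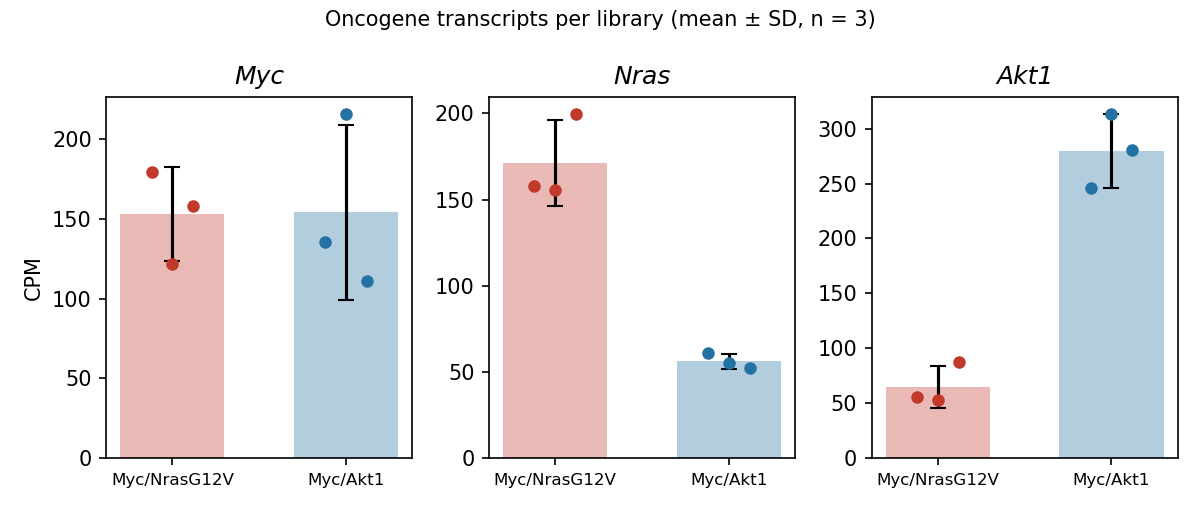
CPM of Myc, Nras and Akt1 in each of the 6 libraries. Bars are group means, error bars are SD (n = 3) and points are libraries; Nras averaged 171 CPM in Myc/NrasG12V against 56.0 in Myc/Akt1, and Akt1 65.1 against 279.9.

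Myc/NrasG12V tumours carried far more transcript of several fetal liver genes and of ERK-induced genes, and Myc/Akt1 tumours more of cell cycle and fatty acid metabolism genes. Those lists passed the set test camera with its preset correlation between genes and not with an estimated one (adjusted p = 0.167 for oncofetal and ERK genes, 0.414 for cell cycle and fatty acid oxidation genes and 0.526 for fatty acid synthesis genes). Afp, the fetal serum protein alpha-fetoprotein, was 1345-fold higher in Myc/NrasG12V, and Car3, a carbonic anhydrase, 399.7-fold higher in Myc/Akt1. Of 14365 genes tested, 5677 differed, 1437 higher in Myc/NrasG12V and 4240 higher in Myc/Akt1. Differences of at least 1 on the log2 scale were found for 3216 of them, 958 higher in Myc/NrasG12V and 2258 higher in Myc/Akt1. The groups did not overlap for 7576 tested genes, or 52.7%, where chance gives 10%. The share of changed genes higher in Myc/Akt1 depended on scaling: it was 74.7% on the CPM scale, 56.5% with TMM factors, 53.4% with median-of-ratios factors and 48.1% with upper-quartile factors. The median log2 difference of all tested genes was -0.26 on the CPM scale, -0.04 with TMM factors, -0.01 with median-of-ratios factors and 0.05 with upper-quartile factors, and the log2 differences below are to be read against that shift. Albumin alone took 11.1 ± 1.77% (SD, n = 3) of the reads in Myc/NrasG12V and 3.36 ± 0.442% (SD, n = 3) in Myc/Akt1. Mitochondrially encoded transcripts took 2.96 ± 0.972% (SD, n = 3) and 8.45 ± 0.754% (SD, n = 3). Myc/NrasG12V replicate 3 stood apart from its group on the second principal component, which held 11.6% of the variance against 75.4% on the first. Without it 6298 genes differed, 1502 higher in Myc/NrasG12V and 4796 higher in Myc/Akt1.

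The 10 largest differences toward Myc/NrasG12V by the rule for named genes were led by Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), at 5415 ± 1416 CPM (SD, n = 3) against 4.03 ± 1.29 CPM (SD, n = 3). Gpc3, a heparan sulfate proteoglycan of fetal liver (ENSMUSG00000055653, chromosome X, 52272426 to 52613950), was 494-fold higher, and the protease inhibitor A2m 401-fold. Tff3, a secreted mucosal peptide, was 882-fold and the tetraspanin Tspan8 286-fold higher. The others were Cacna1b, a neuronal calcium channel subunit (1028-fold, or 657-fold without Myc/NrasG12V replicate 3), Akr1c18 (809-fold), the kinesin Kif5c (493-fold), Cpe, a prohormone carboxypeptidase (289-fold, or 126-fold without Myc/NrasG12V replicate 3) and Serpina1e (107-fold). Tff3, Akr1c18 and Kif5c had only 19, 15 and 17 reads over the Myc/Akt1 group, so the size of their folds is imprecise. Toward Myc/Akt1, Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523) was at 3655 ± 1162 CPM (SD, n = 3) against 9.14 ± 7.80 CPM (SD, n = 3). The carboxylesterases Ces1e, Ces3a and Ces1f were 104-, 89.7- and 73.5-fold higher in Myc/Akt1, and Hamp2 189.5-fold. The aldehyde dehydrogenase Aldh1a1 was 52.1-fold and the peroxisomal thiolase Acaa1b 31.0-fold higher, and Aldh1a7 was at 747 against 11.5 CPM. Mup10, a major urinary protein, was at 97.8 against 0.126 CPM (277-fold higher without Myc/Akt1 replicate 3), and the fatty acid hydroxylase Cyp4a12a had 4554 reads over the group against 4. The limma adjusted p of these 20 genes ran from 5.24e-07 for Afp to 4.77e-04 for Acaa1b. Leaving out 1 library moved the fold over 1.5 times for 23 of the genes named in this part. For 12 of them a fold fell, and those folds are given with the genes; for the other 11 the fold only rose. Serpina1, Ces1, Mup, Cyp4a, Gsta and alpha-globin genes have close copies, so the split of reads among them is uncertain.

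**Figure D2:**
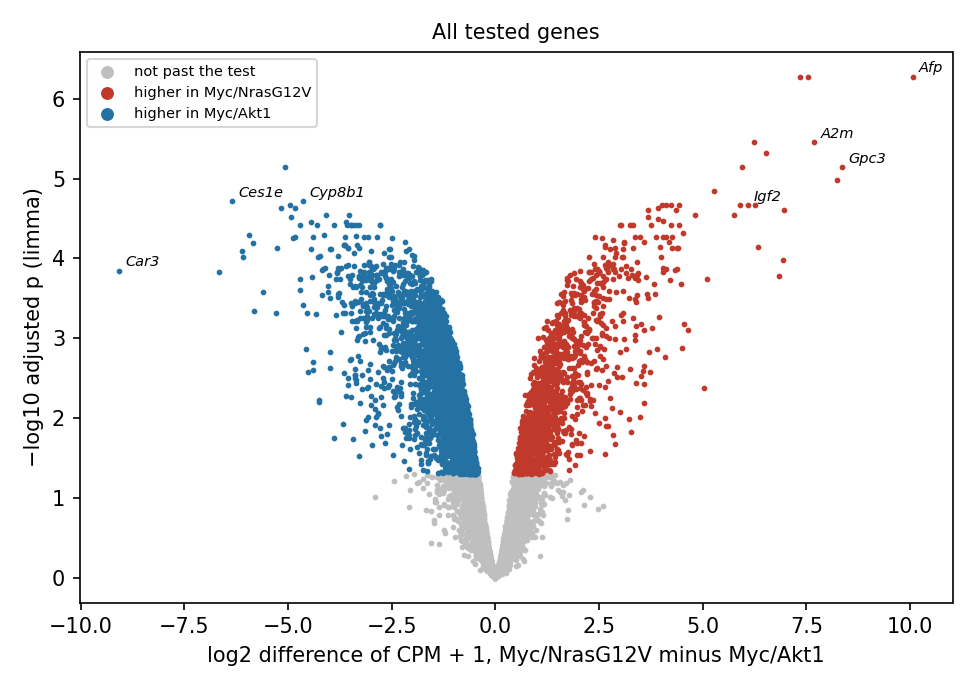
Log2 difference of CPM + 1 (Myc/NrasG12V minus Myc/Akt1) against the −log10 of limma's adjusted p for the 14365 tested genes, as 1 point per gene. The 1437 genes higher in Myc/NrasG12V are red, the 4240 higher in Myc/Akt1 blue and the 8688 that did not pass grey; Afp lies farthest right, at 10.07, and Car3 farthest left, at -9.07.

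Gene lists were tested as sets with camera. Of 31 lists with at least 5 tested members, 19 passed with the preset inter-gene correlation. With a correlation estimated from the libraries camera passed 0, with 4 at an unadjusted p under 0.05, and fry passed 12. Those lost with fry were interferon response (adjusted p = 0.109), MHC class II (0.481), cytokines (0.281), T and NK cells (0.0764), macrophages (0.101), stellate cells (0.0764) and endothelial cells (0.284). The 3 other factors below are TMM, median-of-ratios and upper-quartile factors. Members were called by the limma test over all genes. Members that went against their list, members of a list's small counts and the well known markers given with values that did not pass were chosen after their values were seen, where the rule did not name them.

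Genes switched on by ERK, the kinase downstream of Ras, rose in Myc/NrasG12V. Of 24 tested members 20 were higher, 0 lower and 4, Etv1, Epha2, Epha4 and Areg, not past the test (camera adjusted p = 6.04e-15; adjusted p = 0.167 with an estimated correlation). The ERK phosphatase genes Dusp4, Dusp5 and Dusp6 were 42.5-, 30.1- and 5.47-fold higher, and the early response gene Ier3 28.5-fold. Of 10 oncofetal genes, 6 were higher and 1 lower (camera adjusted p = 5.59e-05; adjusted p = 0.167 with an estimated correlation). Igf2, a fetal growth factor, was at 12365 ± 1049 CPM (SD, n = 3) against 192 ± 77.6 CPM (SD, n = 3). Dlk1, a marker of fetal hepatoblasts, was at 21.4 ± 10.8 CPM (SD, n = 3) and had 0 reads in all 3 Myc/Akt1 libraries, so in pooled reads it was at least 506-fold higher against a floor of 3 reads over that group. The member that was lower, Mest, was at 2.70 against 12.2 CPM. H19, another well known member, was abundant in both groups and did not pass (limma adjusted p = 0.212). It was at 10425 ± 3743 CPM (SD, n = 3) in Myc/NrasG12V and 5892 ± 1594 CPM (SD, n = 3) in Myc/Akt1. Of 15 cholangiocyte and progenitor genes, 7 were higher and 1 lower (camera adjusted p = 4.98e-06; adjusted p = 0.305 with an estimated correlation). Besides Tspan8, the stem cell glycoprotein Prom1 was 23.5-fold and the keratin Krt23 9.72-fold higher, while the epithelial transcription factor Elf3 was 16.0-fold higher in Myc/Akt1. Krt19 and Sox9, widely used markers of the lineage, had log2 differences of 0.69 and 0.74 that did not pass.

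Proliferation genes were much lower in Myc/NrasG12V. Of 27 cell cycle genes, 26 were lower and 1, Ccne1, did not pass, and the median log2 difference was -2.97 (camera adjusted p = 1.57e-10; adjusted p = 0.414 with an estimated correlation). Ccnb2, the mitotic cyclin B2, was at 3.10 ± 0.330 CPM (SD, n = 3) against 45.0 ± 8.57 CPM (SD, n = 3). The same samples had more blood cell transcripts, with median log2 differences of 1.92 for neutrophil and 4.09 for erythroid genes. Cdc20, an activator of mitotic exit, was at 3.77 against 67.7 CPM, and Birc5 and Tk1 were 13.0- and 5.05-fold higher in Myc/Akt1. Of 18 p53 target and CDKN2A locus genes, 6 were higher in Myc/NrasG12V and 1, Perp, lower, and with the 3 other factors 10, 10 and 11 were higher and 1, 1 and 0 lower (camera adjusted p = 5.31e-06; adjusted p = 0.260 with an estimated correlation). Cdkn2a and Cdkn2b, neighbouring genes of cell cycle inhibitors (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, and ENSMUSG00000073802, chromosome 4, 89306299 to 89311039), were at 18.1 ± 4.09 CPM (SD, n = 3) and 17.4 ± 4.28 CPM (SD, n = 3) in Myc/NrasG12V. In Myc/Akt1 they were at 0.317 ± 0.315 CPM (SD, n = 3) and 0.326 ± 0.0546 CPM (SD, n = 3). Btg2 was 9.76-fold and Phlda3 3.32-fold higher in Myc/NrasG12V, and Cdkn1a, the best known p53 target, had a log2 difference of 0.76 that did not pass. Of 25 ribosome biogenesis and MYC target genes, 15 were lower in Myc/NrasG12V on the CPM scale, 5 with TMM or median-of-ratios factors and 3 with upper-quartile factors (camera adjusted p = 0.0116; adjusted p = 0.557 with an estimated correlation). The mitochondrial chaperonin Hspd1 was 3.82-fold higher in Myc/Akt1, and Mrto4, Nolc1 and Eif4a1 2.18-, 1.83- and 1.81-fold. The calls of gene Nolc1 and gene Eif4a1 ended with upper-quartile factors (adjusted p = 0.0602 and 0.0684), and that of Eif4a1 with edgeR (adjusted p = 0.0619). Over the alternatives their adjusted p ran from 0.00455 to 1.00 and from 0.00488 to 1.00, the highest in the test against a fold of 2. This count fell to 6 without Myc/NrasG12V replicate 1, to 6 without Myc/Akt1 replicate 1 and to 8 without Myc/Akt1 replicate 2.

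**Figure D3:**
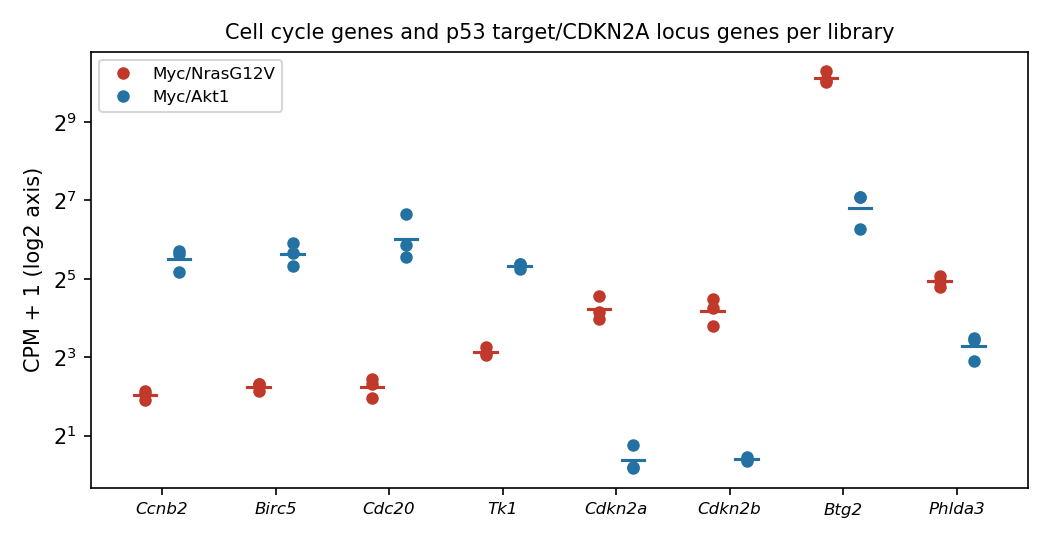
CPM + 1 on a log2 axis in each of the 6 libraries for 4 cell cycle genes and 4 genes of the p53 target and CDKN2A locus list, with points for libraries and short lines for means on the log scale (n = 3). Ccnb2, Birc5, Cdc20 and Tk1 were lower in every Myc/NrasG12V library than in every Myc/Akt1 library, and Cdkn2a, Cdkn2b, Btg2 and Phlda3 were higher.

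Fatty acid and bile acid genes were higher in Myc/Akt1. With the 3 other factors the counts below toward Myc/Akt1 became 14, 13 and 13 for fatty acid synthesis and 18, 18 and 16 for fatty acid oxidation. They became 9 with each factor for bile acid genes and for NRF2 targets. Of 23 genes of fatty acid and triglyceride synthesis, 17 were higher in Myc/Akt1 and 0 lower (camera adjusted p = 2.62e-04; adjusted p = 0.526 with an estimated correlation). Me1, which makes NADPH for lipid synthesis, was at 255 ± 72.5 CPM (SD, n = 3) in Myc/Akt1 against 7.30 ± 2.07 CPM (SD, n = 3), and Thrsp, Agpat2 and the citrate carrier Slc25a1 were 22.0-, 3.53- and 2.11-fold higher. Thrsp was 13.3-fold higher without Myc/Akt1 replicate 3. Of 21 genes of the opposite pathway, fatty acid oxidation, and PPARA targets, 19 were also higher in Myc/Akt1 and 0 lower (camera adjusted p = 1.12e-06; adjusted p = 0.414 with an estimated correlation). The hydroxylases Cyp4a14 and Cyp4a10 were 19.6- and 9.61-fold, Acot1 30.3-fold and Cpt2, of mitochondrial fatty acid import, 7.75-fold higher. Of 16 bile acid genes, 11 were higher in Myc/Akt1 (camera adjusted p = 0.00671; adjusted p = 0.414 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase, was 27.6-fold, Baat 7.25-fold, the bile acid receptor gene Nr1h4 4.30-fold and the uptake carrier Slc10a1 3.66-fold higher there. The 1 member lower in Myc/Akt1, Nr0b2, encodes a repressor of bile acid synthesis genes. Lower there were 0 without Myc/NrasG12V replicate 2 or any 1 of the Myc/Akt1 libraries, and 2 without Myc/NrasG12V replicate 1. Of 19 NRF2 targets, 13 were higher and 2, Osgin1 and G6pdx, lower in Myc/Akt1 (camera adjusted p = 0.0369; adjusted p = 0.526 with an estimated correlation). Gsta1 and Pgd were 34.4- and 3.14-fold higher in Myc/Akt1, Gclm was at 370.0 against 80.5 CPM, and Osgin1 was 6.43-fold higher in Myc/NrasG12V. The NRF2 set call ended with a filter of 1 CPM in 3 libraries (adjusted p = 0.0530), a pseudocount of 0.1 (0.0512) and without Myc/Akt1 replicate 1 (adjusted p = 0.0655; range over the alternatives with the preset correlation 0.0109 to 0.0655).

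Other metabolic and stress lists did not pass the set test. Of 25 cholesterol synthesis genes, 13 were higher in Myc/Akt1 and 1 lower (camera adjusted p = 0.0747), with 5, 5 and 4 higher in Myc/Akt1 under the 3 other factors and 7 without any 1 of the Myc/Akt1 libraries. Lower in Myc/Akt1 were 3 without Myc/NrasG12V replicate 3 and 0 without Myc/NrasG12V replicate 1 or 2 or Myc/Akt1 replicate 1. Acat2 and Ebp were 4.27- and 4.04-fold higher in Myc/Akt1. Of 19 glycolysis genes, 6 were higher in Myc/Akt1 and 2, Slc2a1 and Pfkfb3, in Myc/NrasG12V (camera adjusted p = 0.782). Eno1 and Pgam1 were 5.70- and 3.32-fold higher in Myc/Akt1, and the list's median log2 difference, -0.16, had the opposite sign to camera. With each of the 3 other factors 5 were higher in each group, and the median was 0.09 to 0.19. Without Myc/NrasG12V replicate 2 or Myc/Akt1 replicate 2 or 3 only 1 was higher in Myc/NrasG12V. Among 20 FOXO-regulated and gluconeogenic genes Pck1, Igfbp1 and Cited2 were higher in Myc/NrasG12V and G6pc, Fbp1, Sesn3 and Pdk4 in Myc/Akt1 (camera adjusted p = 0.0720). The counts became 5 and 3 with TMM or median-of-ratios factors and 6 and 3 with upper-quartile factors. The call of Pdk4 ended with each of the 3 other factors and without Myc/NrasG12V replicate 1 or 3 or Myc/Akt1 replicate 1 or 2, and that of Pck1 without Myc/NrasG12V replicate 2 or any 1 of the Myc/Akt1 libraries. Igfbp1, which insulin represses, was at 5092 ± 1281 CPM (SD, n = 3) in Myc/NrasG12V against 262 ± 139 CPM (SD, n = 3), and Fbp1, of gluconeogenesis, was 4.94-fold higher in Myc/Akt1. Of 20 ATF4 and unfolded protein response genes, 3 were higher in Myc/NrasG12V and 5 in Myc/Akt1 (camera adjusted p = 0.0817), with Psat1 and Xbp1 4.76- and 3.11-fold higher in Myc/NrasG12V. Its 3 became 7 with each of the 3 other factors, 6 without Myc/NrasG12V replicate 3 and 5 without Myc/Akt1 replicate 3. Its 5 became 4, 4 and 3 with the 3 other factors. Of 14 YAP targets, Ctgf (2.52-fold) and Ankrd1 were higher in Myc/NrasG12V and Amotl2 (2.33-fold) in Myc/Akt1 (camera adjusted p = 0.0608). Higher in Myc/NrasG12V were 6 with each of the 3 other factors, 4 without Myc/NrasG12V replicate 3 and 1 without Myc/Akt1 replicate 2 or 3. Without Myc/NrasG12V replicate 1 or 3, 2 were higher in Myc/Akt1. Of 19 invasion and mesenchymal genes, 4 were higher in Myc/NrasG12V, with Plaur at 4.62-fold, and 3 in Myc/Akt1, with Lgals1 at 8.79-fold (camera adjusted p = 0.0608). The 4 became 6, 6 and 7 with the 3 other factors, 2 without Myc/NrasG12V replicate 1 and 1 without Myc/Akt1 replicate 2 or 3.

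Hepatocyte genes went both ways. Of 24 hepatocyte function genes, 6 were higher in Myc/NrasG12V, the plasma protein genes Apoa1, Fgb, Trf, Serpina1c, Ahsg and F2, and 7 in Myc/Akt1, among them the enzyme genes Otc, Cyp3a11, Tdo2, Ugt2b1 and Cyp2c29 (camera adjusted p = 0.0817). The 7 became 3, 2 and 2 with the 3 other factors and 4 without Myc/Akt1 replicate 3. The median log2 difference was -0.18, the mean 0.13, and camera pointed to higher in Myc/NrasG12V. Trf, transferrin, and Fgb, fibrinogen beta, were 5.85- and 4.20-fold higher in Myc/NrasG12V. The gene Alb had a log2 difference of 1.72 that did not pass, with a limma adjusted p of 0.184, although edgeR on the recovered reads called it (adjusted p = 0.00501; range over the alternatives 4.26e-14 to 0.740). It was also called with a single variance prior, robust edgeR, the test against a fold of 2, DESeq2 and limma-voom. The fit with a single prior differed from the main fit only in that variance was not tied to expression level. That tie, and not the spread of Alb alone, therefore kept Alb from passing. Alb took 9.07 to 12.4% of the reads in the Myc/NrasG12V libraries and 2.99 to 3.85% in the Myc/Akt1 libraries, without overlap. Of 13 periportal genes, 4 were higher in Myc/NrasG12V and 4 in Myc/Akt1, with Cyp2f2 29.3-fold and Igfals 8.65-fold higher there (camera adjusted p = 0.478). Of these, 2 were higher in Myc/NrasG12V without Myc/Akt1 replicate 1 and 2 in Myc/Akt1 without Myc/Akt1 replicate 2. The median log2 difference of the periportal list was -0.24 while camera pointed to higher. Of 13 pericentral and beta-catenin target genes, Rnf43 was higher in Myc/NrasG12V, at 24.8 against 7.60 CPM, and Tbx3 lower, at 2.51 against 5.19 (camera adjusted p = 0.858). The call of Tbx3 ended with each of the 3 other factors and without Myc/NrasG12V replicate 1 or any 1 of the Myc/Akt1 libraries (adjusted p over the alternatives 0.0268 to 1.00), and that of Rnf43 without Myc/Akt1 replicate 1. Lower were 3 other genes without Myc/Akt1 replicate 1 and 2 genes without Myc/NrasG12V replicate 2.

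Erythroid and neutrophil genes were higher in Myc/NrasG12V, and other blood cell lists less evenly so. Of 7 erythroid genes 6 were higher and 1, Alas2, did not pass (camera adjusted p = 4.98e-06; adjusted p = 0.414 with an estimated correlation), with Hbb-bs at 620.1 ± 461 CPM (SD, n = 3) against 19.5 ± 10.1 CPM (SD, n = 3), 19.8-fold higher without Myc/NrasG12V replicate 3. Hbb-bt and Hba-a1 were 32.5- and 31.7-fold higher (Hba-a1 17.0-fold without Myc/NrasG12V replicate 3), and the red cell membrane gene Slc4a1 was at 11.1 against 0.0566 CPM. Of 14 neutrophil genes, 12 were higher and 1, Hdc, which makes histamine, lower (camera adjusted p = 1.20e-07; adjusted p = 0.414 with an estimated correlation). With upper-quartile factors 0 were lower. S100a8 and S100a9 were 43.5- and 40.7-fold higher, Mmp8 29.4-fold and the growth factor receptor gene Csf3r 5.12-fold. Without Myc/NrasG12V replicate 3 S100a8, S100a9 and Mmp8 were 20.9-, 20.7- and 18.3-fold higher. Mmp8 had only 9 reads over the Myc/Akt1 group. Of 18 T and NK cell genes, 9 were higher and 1, Klrb1c, lower (camera adjusted p = 4.98e-06; adjusted p = 0.422 with an estimated correlation), at low levels: Pdcd1 was at 4.84 ± 4.25 CPM (SD, n = 3) against 0.0869 ± 0.0849 CPM (SD, n = 3). Ccl5, Gzmb and Ctla4 were 9.75-, 7.22- and 16.0-fold higher. Without Myc/NrasG12V replicate 1 Pdcd1 was 27.7-fold and Ccl5 5.08-fold higher. The call of Klrb1c ended with each of the 3 other factors and without Myc/NrasG12V replicate 1 or Myc/Akt1 replicate 2 or 3. Of 21 macrophage and monocyte genes, 6 were higher and 0 lower, and 10 were higher with each of the 3 other factors (camera adjusted p = 2.33e-04; adjusted p = 0.422 with an estimated correlation). Marco, Cd163, Vsig4 and Mrc1, of resident macrophages, were 6.14-, 3.57-, 3.24- and 1.74-fold higher. In Myc/Akt1, 1 of 7 B and plasma cell genes was higher, Mzb1 (5.44-fold; camera adjusted p = 0.293), and 1 of 8 dendritic cell genes, Itgax (2.18-fold; camera adjusted p = 0.401). Mzb1 had only 15 reads over the Myc/NrasG12V group. The dendritic median log2 difference was -0.07 while camera pointed to higher in Myc/NrasG12V. The call of Itgax ended with each of the 3 other factors and without Myc/NrasG12V replicate 2 or 3 or Myc/Akt1 replicate 1 or 2 (adjusted p over the alternatives 0.0179 to 1.00). With the 3 other factors 1, 1 and 2 B and plasma cell genes and 1, 1 and 2 dendritic cell genes were higher in Myc/NrasG12V.

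Some vessel and matrix genes rose in Myc/NrasG12V. Of 17 endothelial genes, 6 were higher and 2, Cdh5 and Cd34, lower (camera adjusted p = 0.0273; adjusted p = 0.526 with an estimated correlation). Lower were 1, 0 and 0 with the 3 other factors and 0 without Myc/Akt1 replicate 1, and 1 without Myc/NrasG12V replicate 1 or 3 or Myc/Akt1 replicate 2. Higher were the sinusoidal genes Stab1, Lyve1 and Gpr182, at 2.68-, 2.82- and 2.89-fold, and Vwf, of larger vessels, at 6.03-fold. The endothelial set call ended with no filter beyond 1 read (adjusted p = 0.0721) and without Myc/NrasG12V replicate 2 (adjusted p = 0.170; range 0.00627 to 0.170). Of 19 stellate cell, fibroblast and matrix genes, 4 were higher and 1, Postn, lower (camera adjusted p = 0.0129; adjusted p = 0.422 with an estimated correlation). The call of Postn ended with each of the 3 other factors and without Myc/NrasG12V replicate 1 or 3 or Myc/Akt1 replicate 1 or 2. Without Myc/NrasG12V replicate 2, 2 genes of the list were lower. Timp1, Reln, Pdgfra and Dcn were 10.8-, 5.45-, 3.63- and 2.57-fold higher, while the collagen genes Col1a1 and Col3a1 had log2 differences of -0.45 and -0.49 that did not pass. The set call ended without Myc/Akt1 replicate 3 (adjusted p = 0.0692; range 0.00197 to 0.0692). Of the pancreas list only Cela1 was tested, 2.89-fold higher in Myc/NrasG12V, and of 3 tested adipocyte genes Cidec was 15.9-fold higher in Myc/Akt1, or 7.40-fold without Myc/Akt1 replicate 1.

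Interferon response genes were higher in Myc/Akt1 for 10 of 23 members and lower for 0, with 6, 6 and 5 higher under the 3 other factors (camera adjusted p = 0.0273; adjusted p = 0.658 with an estimated correlation). Oasl1, Mx1, Rsad2 and Ddx58 were 7.32-, 5.28-, 4.15- and 2.02-fold higher. The call of gene Ddx58 ended with upper-quartile factors (adjusted p = 0.0502; range over the alternatives 0.00486 to 1.00). The set call ended without Myc/NrasG12V replicate 3 (adjusted p = 0.263) and without Myc/Akt1 replicate 3 (adjusted p = 0.0956, with 6 members; range 6.51e-04 to 0.263). Of 15 cytokine and chemokine genes, 4 were higher in Myc/NrasG12V and 2 in Myc/Akt1 (camera adjusted p = 0.0283; adjusted p = 0.526 with an estimated correlation). The neutrophil attractant Cxcl1 was 4.52-fold and Il1b 7.67-fold higher in Myc/NrasG12V, and the monocyte attractant Ccl2 and Cxcl12 were 4.07- and 2.95-fold higher in Myc/Akt1. The 4 became 2 without Myc/NrasG12V replicate 1 or 2 or Myc/Akt1 replicate 1 or 2. The MHC class II list passed toward Myc/NrasG12V (camera adjusted p = 0.0283; adjusted p = 0.557 with an estimated correlation), although limma passed 0 of its 9 members, with 1 at an unadjusted p under 0.05, and edgeR 2. Limma passed 1 of them without Myc/NrasG12V replicate 2 and 2 without Myc/NrasG12V replicate 3. The cytokine call ended without Myc/NrasG12V replicate 1 (adjusted p = 0.113) or 2 (adjusted p = 0.0861; range 0.00157 to 0.113), and the MHC class II call without Myc/NrasG12V replicate 1 (adjusted p = 0.314) or Myc/Akt1 replicate 3 (adjusted p = 0.0692; range 0.00150 to 0.314). Both ended with TMM (adjusted p = 0.0591 for each), median-of-ratios (0.0638) and upper-quartile factors (0.0770). Of 15 MHC class I genes, H2-K1, H2-D1 (741 against 370.2 CPM) and Nlrc5 (2.32-fold) were higher in Myc/NrasG12V and Erap1 and Canx in Myc/Akt1 (camera adjusted p = 0.138). With each of the 3 other factors 4 were higher in Myc/NrasG12V and 0 in Myc/Akt1. Without Myc/Akt1 replicate 1 or 2 the counts were 2 and 0, without Myc/NrasG12V replicate 1 they were 2 and 1, and without Myc/NrasG12V replicate 3 they were 5 and 2.

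Of the lists that did not pass, 7 passed with a setting changed or 1 library left out. Cholesterol synthesis passed with median-of-ratios (0.0465) and upper-quartile factors (0.0374), with no filter (0.0336), with the replicate number as a block (0.0415) and without Myc/NrasG12V replicate 1 (0.0229) or 2 (0.00270) or Myc/Akt1 replicate 1 (0.0456; range of adjusted p 0.00270 to 0.710). Without Myc/NrasG12V replicate 3, 5 passed: ATF4 (range 0.0168 to 0.354), YAP (range 0.0310 to 0.134), FOXO (range 0.0261 to 0.175), MHC class I (range 0.0193 to 0.461) and hepatocyte function, toward Myc/NrasG12V (range 0.0315 to 0.251). Invasion genes passed without Myc/NrasG12V replicate 1 or Myc/Akt1 replicate 1 (range 0.0294 to 0.190), YAP targets also without Myc/Akt1 replicate 1 or 2, and FOXO genes also without Myc/Akt1 replicate 2. FOXO and YAP genes passed with a pseudocount of 5 as well, and YAP targets with the replicate number as a block (adjusted p = 0.0445).

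Small counts moved in other lists too. Without Myc/NrasG12V replicate 3, 1 gene each went against the ERK, fatty acid synthesis, interferon and macrophage lists and 2 against the oncofetal list. Without Myc/Akt1 replicate 3, 2 genes of the p53 list were lower in Myc/NrasG12V. With each of the 3 other factors 1 cell cycle and 1 MHC class II gene were higher there.

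Adjusted over the list alone, the counts differed for 13 lists. Higher in Myc/NrasG12V were then 3 glycolysis, 5 ATF4, 1 cell cycle, 9 cholangiocyte, 12 T and NK cell, 13 neutrophil and 1 adipocyte genes. Higher in Myc/Akt1 were 19 fatty acid synthesis, 11 interferon, 3 cytokine, 2 oncofetal, 2 T and NK cell, 0 pericentral and 0 dendritic cell genes.

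**Figure D4:**
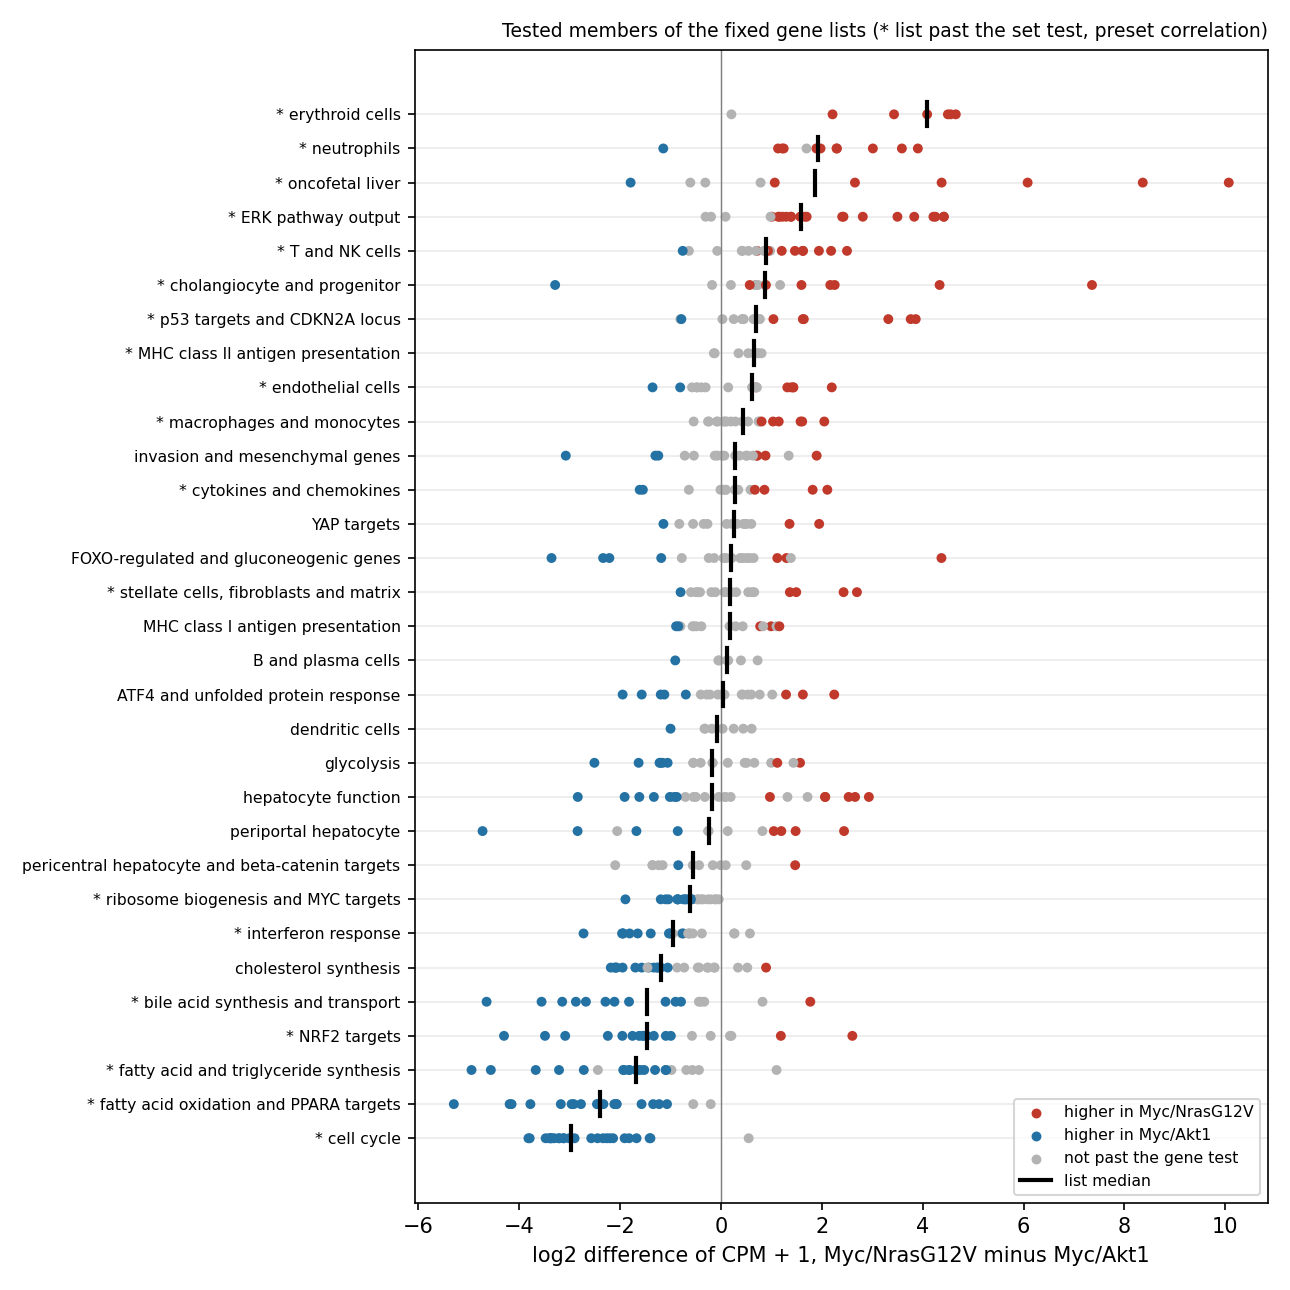
Log2 difference of CPM + 1 (Myc/NrasG12V minus Myc/Akt1) of each tested member of the 31 gene lists with at least 5 tested members, as 1 point per gene, red higher in Myc/NrasG12V, blue higher in Myc/Akt1 and grey not past the limma test. Black bars are list medians, from -2.97 for cell cycle to 4.09 for erythroid genes, and an asterisk marks the 19 lists past camera with the preset correlation.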

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

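TMM factors, pseudocounts of 0.1 and 5, a single variance prior and edgeR on the recovered reads were added after seeing the data, as was the reason for leaving out Myc/NrasG12V replicate 3; the other settings were planned. Total-count scaling equals CPM here and gives no separate value. The total of 5677 changed genes stayed within 1.5 times, and the direction counts kept that too, under the filters (5325 with none, 5479 at 1 CPM in 3 libraries), pseudocounts (5690 at 0.1, 5489 at 5) and the single prior (5592). With the replicate number as a replicate block 5530 genes passed, 5234 of them shared in direction. Samples of the same number correlated weakly once group means were removed (-0.0812, 0.113 and 0.0848). Replicate 2 of each group was still the best match of replicate 2 of the other, and likewise replicate 3, but not replicate 1. A link between samples by number is therefore not excluded. No setting called a gene in the opposite direction.

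Genes higher in Myc/NrasG12V and in Myc/Akt1 numbered 2286 and 2623 with median-of-ratios factors, 2539 and 2350 with upper-quartile factors, and 2791 were higher in Myc/Akt1 with TMM factors. They numbered 2381 and 2512 with edgeR, 2385 and 2514 with its robust form and 2341 and 2499 with limma-voom, and 2768 were higher in Myc/NrasG12V with DESeq2. These 7 settings rescale the libraries. The share of changed genes higher in Myc/Akt1 was 48.9% with the 50 most abundant genes removed (2474 and 2367), which took 40.7% of the reads in Myc/NrasG12V and 23.6% in Myc/Akt1, and 74.6% with every library thinned to the shallowest (1432 and 4216). Removing those 50 genes raises the CPM of the rest more in Myc/NrasG12V, as the factors do, so it is not an independent test. The abundant transcripts stay a candidate explanation for the uneven split, and depth does not. A test against a fold of 2 called 1404 genes (759 and 645), by its stricter construction.

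Without each library in turn the total ran from 3856 (without Myc/Akt1 replicate 1) to 6298, genes higher in Myc/NrasG12V from 966 to 1502, higher in Myc/Akt1 from 2890 to 4796 and lists from 16 to 23. Log2 differences ran from -2.34 to -1.99 for Akt1, 1.47 to 1.65 for Nras and -0.18 to 0.30 for Myc, which changed sign and never passed. Lists past the set test numbered 0 with an estimated correlation and 12 with fry.

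Xist, which never passed, changed sign: its log2 difference was 0.28 with median-of-ratios, 0.34 with upper-quartile and 0.24 with TMM factors, 0.30 with edgeR in its 3 forms, 0.28 with DESeq2, 0.29 with limma-voom and -0.11 to 0.10 without single libraries. Lists that never passed also turned: glycolysis with no filter (adjusted p = 0.910), fry (0.281) and without Myc/Akt1 replicate 3 (single libraries left out gave 0.461 to 0.966). Pericentral genes turned with the 1 CPM filter (0.9495), a pseudocount of 5 (0.929) and without Myc/NrasG12V replicate 3, Myc/Akt1 replicate 2 or Myc/Akt1 replicate 3 (single libraries left out gave 0.264 to 0.851), and with fry periportal (0.426) and dendritic genes (0.967). The cause was not tested. Of 115 named genes followed over 20 settings, 91 kept their call in each. At 3 libraries per group a 1.5-fold change was recovered for 27.3% of simulated genes, which had a common dispersion and a mean of at least 5 CPM.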

Other observations

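The gene families below, the imprinted and precursor lists, and the tests of tumour cell share, of uninvolved liver, of imprinted genes and of precursor against erythroid folds were chosen after results had been seen. Genes of mitochondrial protein synthesis and respiration and of the proteasome were higher in Myc/Akt1. Of 75 mitochondrial ribosomal protein genes (Mrp), 57 were higher in Myc/Akt1 and 0 lower, and 46, 42 and 34 with TMM, median-of-ratios and upper-quartile factors (camera adjusted p = 1.91e-08; adjusted p = 0.462 with an estimated correlation). Of 45 genes of respiratory complex I (Nduf), 36 were higher in Myc/Akt1 and 0 lower, and 27, 26 and 24 with those factors (camera adjusted p = 1.75e-06; adjusted p = 0.462 with an estimated correlation). Of 39 proteasome genes (Psm), 27 were higher in Myc/Akt1, and 22, 16 and 14 with those factors, the last with 2 lower (camera adjusted p = 2.93e-04; adjusted p = 0.462 with an estimated correlation). Of 11 mitochondrially encoded genes 7 were higher in Myc/Akt1, and 5, 5 and 4 with those factors, the last with 1 lower, but 2 without Myc/NrasG12V replicate 1, 4 without Myc/NrasG12V replicate 2 and 4 without Myc/Akt1 replicate 2 (camera adjusted p = 0.0282; adjusted p = 0.462 with an estimated correlation). Cytoplasmic ribosomal protein genes had 6 higher and 3 lower of 77 in Myc/NrasG12V, and 30, 33 and 39 higher and 0 lower with those factors (camera adjusted p = 1.56e-05; adjusted p = 0.628 with an estimated correlation). Their count also moved with single libraries, from 0 higher without Myc/Akt1 replicate 2 to 18 without Myc/Akt1 replicate 3. Of 14 glucuronosyltransferase genes (Ugt) 11 were higher in Myc/Akt1, and 9 with each of those factors (camera adjusted p = 0.00134; adjusted p = 0.462 with an estimated correlation). Of 19 glutathione transferase genes (Gst) 13 were higher in Myc/Akt1, and 9 with each of those factors and then 1 lower (camera adjusted p = 0.00576; adjusted p = 0.465 with an estimated correlation). Sulfotransferase genes (Sult) went both ways, with 4 of 17 higher in each group (camera adjusted p = 0.0803; adjusted p = 0.628 with an estimated correlation). The p-values were adjusted over 22 families.

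Serpin genes, many of them of secreted protease inhibitors, had 16 higher and 7 lower of 33 in Myc/NrasG12V, and 17 and 5 with TMM factors (camera adjusted p = 8.19e-05; adjusted p = 0.462 with an estimated correlation). The metallothionein genes Mt1 and Mt2 were 4.39- and 4.95-fold higher in Myc/NrasG12V. Imprinted noncoding RNAs next to Dlk1 were also higher there: Meg3 was at 289.7 ± 8.87 CPM (SD, n = 3) against 3.18 ± 2.29 CPM (SD, n = 3), Rian at 177 against 2.36 CPM and Mirg at 13.7 against 0.141 CPM. Of 26 tested imprinted genes, 8 were higher in Myc/NrasG12V, 3 higher in Myc/Akt1 and 15 did not pass (camera p = 3.06e-04; p = 0.0266 with an estimated correlation). Without the 9 genes whose values had prompted the list, 1 of 17 was higher and 2 were lower. The camera p of those 17 was 0.581, so the set result rests on the genes that prompted it. The chemokine gene Cxcl17 was at 62.9 ± 29.7 CPM (SD, n = 3) in Myc/NrasG12V with 0 reads in Myc/Akt1, in pooled reads at least 1562-fold higher against 3 reads over the group.

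Cell cycle genes were lower in Myc/NrasG12V, 26 of 27 of them under each of 3 other factors, which argues against scaling of the libraries as the whole cause. A lower share of tumour cells would lower Myc too if its counts come from the transposon, and the lower 95% bound of the log2 difference of Myc, -0.57, lay above -1.48, 0.5 times the median of the cell cycle genes. Markers of other cell types mostly moved toward Myc/NrasG12V, as a lower share of tumour cells would give, with median log2 differences of 4.09 for erythroid cells, 1.92 for neutrophils, 0.89 for T and NK cells, 0.62 for endothelial cells, 0.43 for macrophages, 0.18 for stellate cells, 0.12 for B and plasma cells and -0.07 for dendritic cells. An even rise of all other cell types would raise their markers alike, apart from an effect of the pseudocount. It shrinks the log2 differences of markers near or below 1 CPM, so medians of lists at low levels are understated. Pdcd1, for example, was 55.7-fold higher but had a log2 difference of 2.19. The quartiles of erythroid (2.82 to 4.53) and neutrophil genes (1.36 to 2.30) lay above those of stellate genes (-0.30 to 0.64), which argues against an even rise only. A lower share of tumour cells through a rise of some cell types, such as blood cells, would be uneven too. The quartiles do not decide on that. In Myc/NrasG12V the 4 named erythroid genes were at 11.1 to 620.1 CPM and the 4 named neutrophil genes at 3.66 to 37.0 CPM. A cell cycle median of -2.97 through these cells alone would need them to supply most of the reads. These levels argue against erythroid cells and neutrophils as the whole cause, although the level within such cells was not measured. The species of the delivered Myc is not known, so part of the difference may still lie in cell composition, and the difference in oncogene stays open, untested.

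Genes of fatty acid oxidation and bile acid metabolism were higher in Myc/Akt1, while hepatocyte function genes went both ways. A candidate explanation, uninvolved liver in the Myc/Akt1 samples, would bring all its abundant transcripts, yet 7 of 24 hepatocyte function genes were higher in Myc/Akt1 and 6 were lower. With TMM, median-of-ratios and upper-quartile factors 3, 2 and 2 were higher in Myc/Akt1 and 6, 6 and 7 lower. These factors moved the count away from what uninvolved liver would give, but neither direction held most of the 24 genes. The count decided neither way, so uninvolved liver and a difference between the tumour cells cannot be told apart. The 6 genes lower in Myc/Akt1 on the CPM scale were plasma protein genes such as Trf, at 885 against 5173 CPM. Ttr, Apob, Hpx and C3, plasma protein genes of the same list, were not among them, and that grouping was made after the values were seen. Both an uneven mixture and a difference in the tumours' own programme may contribute.

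Erythroid and neutrophil genes were higher in Myc/NrasG12V. A candidate explanation is peripheral blood left in the samples, and the bound set against it before the test was met: 15 of 17 precursor genes had every Myc/NrasG12V library above every Myc/Akt1 library, as had 14.8% of all tested genes. That bound was wrong, since blood that raised Hbb-bs 31.7-fold would lift its rare transcripts too, and 10 of the 17 were below 1 CPM in Myc/NrasG12V. In pooled reads the median of all 17 was 8.68- to 13.7-fold, since 4 had 0 reads in Myc/Akt1 and only lower bounds, below the 31.7-fold of erythroid and 24.9-fold of neutrophil genes, while Ctsg and Rhag, each with 1 read in Myc/Akt1, rose more than both. No table gives the level of these transcripts in blood, so blood and cells that belong to the tissue cannot be told apart, and the difference in oncogene stays open, untested.

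With 3 samples against 3 the 10 splits of the samples are too few for a share under 0.05: 1 of the 10 gave as many genes, the real one with 5677, and the highest of the others gave 0.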
